A study of Homo sapiens with 4 samples.

How the data were processed

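Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in Ishikawa cells, an established human endometrial adenocarcinoma line. Per the labels, cells grown in phenol red-free medium with charcoal-treated serum were treated for 1 hour with vehicle (DMSO), 100 nM dexamethasone (a synthetic glucocorticoid that activates the glucocorticoid receptor), 10 nM estradiol (the ligand of the estrogen receptor), or both hormones. There were 4 libraries, 1 per treatment, so no spread between replicates could be measured. Groups were taken from the treatment label of each sample.

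The deposited files are 1 peak table per library. Per the file headers, the authors called peaks with MACS 2.1.0.20140616 on each library alone, without pooling and without a control library, at a p cutoff of 1e-10, with an effective genome size of 2.7 Gb, a local background window of 10000 bp and at most 1 tag per position. The submitters' processing notes name Bowtie 1.1.2 and the hg19 build; their role is not stated there. Per the file headers, no shift or fixed extension was set: tags of 50 bp were extended to a fragment length modelled from the data, which was 104 bp for vehicle, 89 bp for dexamethasone, 84 bp for estradiol and 51 bp for the combination. Heights therefore count extended tags and not transposase cut sites, and a shorter modelled length lowers both the height and its background. The pileup signal deposited by the authors is the whole number of extended tags over the summit, not scaled to depth. The deposited fold enrichment is a ratio of the pileup to the same library's local background, each with 1 added. The deposited p-values and q-values are given as −log10 and compare the pileup with that background; the headers say that q was not calculated, but the column holds values. Start, end and summit are deposited positions on hg19, counted from 1. These per-region values are the authors' own and were used to describe, rank or filter regions within one list. The call-probability predictions and the simulations also carried the pileup, and a background derived from the fold enrichment, from one library to another.

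Per the file headers, the libraries held 15922261 tags for vehicle, 24950579 for dexamethasone, 28148235 for estradiol and 12843911 for the combination, and 10694743, 14980230, 20185339 and 8240912 tags after duplicate removal. The redundant rate was 0.33, 0.40, 0.28 and 0.36 in the same order. The number of regions a caller finds moves with this depth and with the modelled fragment length.

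Regions were counted as overlapping when they shared at least 1 bp. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only, and regions are not replicates, so no p-value was computed between treatments. The overlap shares of whole lists, the shares with a neighbour within 10 kb and the highest 1 Mb windows were set beside 1000 random placements of the list on its own chromosomes, within the furthest position called in any list (bedtools 2.31.1). Placement was uniform and did not follow gene density or mappability. A region was called gained when it overlapped no region of the comparison list, and lost in the reverse case; the words describe list membership. Lists were also compared at equal length by the strongest N regions of each by p-value, N being the length of the shorter list. Regions of all lists that overlapped were merged to count membership. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

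To weigh depth, the pileup and background of each nuclear region of a list were scaled by the ratio of tags times fragment length of another library, and the Poisson probability of passing the cutoff was summed over regions. The rule took depth to account for an excess when at least 90% of the regions with a probability above 0.95 were called, with an interval above 75%. It counted depth as excluded when the interval lay below 75%. Because called heights are selected to be high, the sum was repeated with every height lowered by 1 and by 1.5 counting SDs. The minimum peak length of the caller was not modelled, so predicted calls may be too many and a low share does not by itself exclude depth. On simulated data for the prediction of vehicle calls from the 8421 nuclear dexamethasone regions, a planted factor of 0.5 was recovered as 0.507, and planted overlaps were recovered exactly. The simulated calls followed the same Poisson rule as the fit. They check the code and not the assumptions about peak length, selected heights or scaling by fragment length.

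The main settings, the rule for named regions, the gene lists, the motifs and most alternatives were fixed before the data were examined. Alternatives were a −log10 q of at least 10, a fold enrichment of at least 5, chromosomes 1 to 22 and X only, an overlap of at least 50% of the shorter region, regions extended by 500 bp, and lists of equal length. Named regions are, for each treated list, the 10 with the highest fold enrichment that overlap no vehicle region on chromosomes 1 to 22 or X, the 5 highest vehicle regions not in that list, and the 5 highest regions in all lists. The last are ranked by fold enrichment in the vehicle list, a choice made after the values were seen. Further regions are named as chosen after their values were seen. Regions were not filtered here for repeated or poorly mappable sequence, so named regions were not checked for mapping artefacts. Motif content, position relative to genes and the preset gene lists (glucocorticoid-induced, estrogen-induced, steroid receptor, AP-1, endometrial epithelial, housekeeping, stromal, leukocyte, endothelial, and liver and neural genes) were not analysed here, because a genome and gene annotation of the hg19 build were not used here; regions are therefore named by position.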

Results

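Accessible chromatin was mapped in Ishikawa endometrial cancer cells after 1 hour of vehicle, dexamethasone, estradiol or both hormones, with 1 library for each treatment. The comparisons address how activation of the glucocorticoid receptor and the estrogen receptor, alone and together, changes open chromatin in this line. The vehicle list held 1923 regions, the dexamethasone list 8428, the estradiol list 4772 and the combination list 146. These came from 10694743, 14980230, 20185339 and 8240912 tags after duplicate removal, so the order of the lists did not follow depth: the estradiol library was the deepest and the dexamethasone library had the longest list. Per 1000000 tags, 180 regions were called with vehicle, 563 with dexamethasone, 236 with estradiol and 17.7 with the combination. The regions covered 331 kb, 1465 kb, 751 kb and 14.7 kb, and their median lengths were 150, 152, 137 and 65 bp. Since each treatment had a single library, the differences below describe these libraries and have no replicate check.

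**Figure D1:**
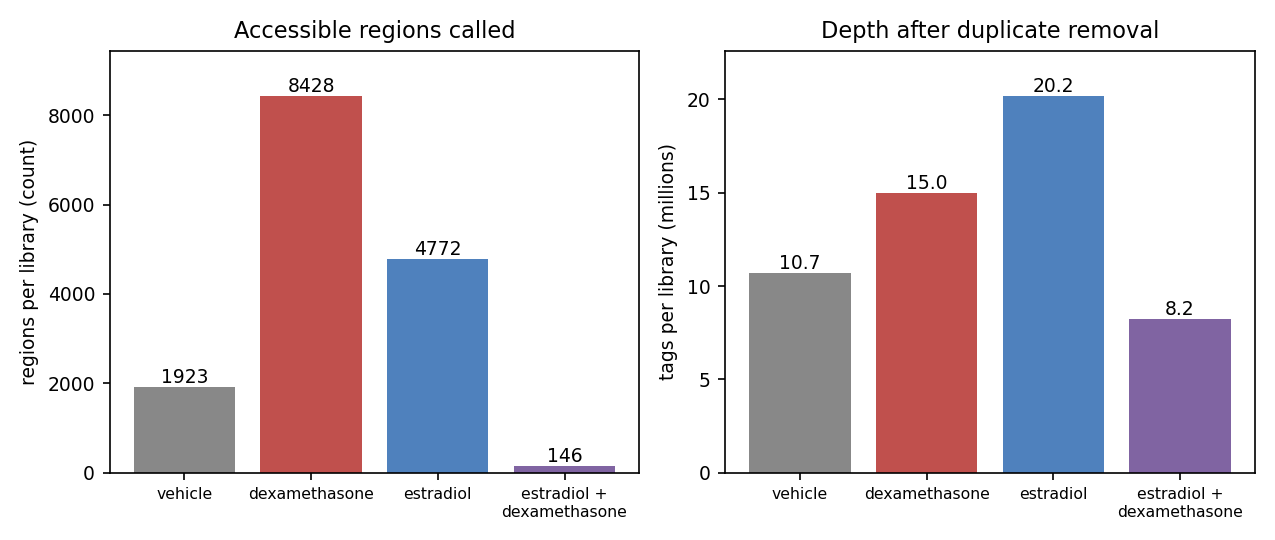
Number of accessible regions called (left, count) and tags after duplicate removal (right, in units of 1000000) in each of the 4 libraries, 1 library per bar and no error bars because there were no replicates. The dexamethasone library had 8428 regions from 14980230 tags, the deeper estradiol library 4772 from 20185339, and the combination library 146 from 8240912.

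Dexamethasone was compared with vehicle first. Nearly every region open in vehicle was also called after dexamethasone, and many more regions were called without a vehicle counterpart. Of the 1923 vehicle regions, 1864 overlapped a dexamethasone region (96.9%, 95% interval 96.1 to 97.7), against a mean of 0.217% over 1000 random placements. In the other direction, 1853 of the 8428 dexamethasone regions overlapped a vehicle region (21.99%, 21.1 to 22.9), which left 6575 gained regions and 59 lost ones. The overlap depended on how strong a region was. Among the strongest 10% of the nuclear dexamethasone regions by p-value, 78.8% were also called in vehicle (75.8 to 81.5), and among the weakest 10% 2.97% were (1.93 to 4.35). At equal list length, 60.6% of the 1923 vehicle regions overlapped one of the strongest 1923 dexamethasone regions, with 770 gained and 757 lost.

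The gained dexamethasone region with the highest fold enrichment lay on chromosome 4 from 3957249 to 3957389 (hg19), with an 18.3-fold enrichment over local background and a pileup of 31 tags. The next were on chromosome 2 from 178937439 to 178937615 (17.9-fold, 38 tags), on chromosome 4 from 147866977 to 147867172 (17.4-fold, 45 tags) and on chromosome 9 from 103173970 to 103174186 (17.1-fold, 37 tags). The following 6 lay on chromosome 15 from 101741686, chromosome 9 from 31598085, chromosome 12 from 38676785, chromosome 6 from 75994483, chromosome 7 from 76751852 and chromosome 5 from 171042370, with fold enrichments between 16.6 and 17.0. Of these 10 regions, 8 were also called after estradiol. The exceptions were the region on chromosome 12 from 38676785 to 38676928 (16.9-fold, 26 tags) and the region on chromosome 7 from 76751852 to 76751962 (16.7-fold, 24 tags), which were called in no other library. The highest vehicle regions not called after dexamethasone lay on chromosome 2 from 92281288 to 92281396 (12.7-fold) and from 92296830 to 92296935 (12.6-fold), on chromosome 17 from 22261521 to 22261624 (12.5-fold), on chromosome 4 from 68265526 to 68265645 (12.5-fold) and on chromosome 15 from 79019348 to 79019463 (10.6-fold). The first 4 of these were called in the combination library. The regions named here and below were not checked for mapping artefacts, and a missing call means only below the threshold of that library.

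Estradiol was compared with vehicle in the same way. Most vehicle regions were again called, and fewer regions were added than after dexamethasone although the library was deeper. Of the 1923 vehicle regions, 1676 overlapped an estradiol region (87.2%, 85.6 to 88.6), against 0.170% in random placements, and 247 did not. Of the 4772 estradiol regions, 1680 overlapped a vehicle region (35.2%, 33.8 to 36.6), leaving 3092 gained. Among the strongest 10% of nuclear estradiol regions, 83.0% were called in vehicle (79.3 to 86.3), and among the weakest 10% 13.9% (10.9 to 17.3). At equal list length 57.5% of vehicle regions overlapped one of the strongest 1923 estradiol regions, with 824 gained and 818 lost.

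The gained estradiol region with the highest fold enrichment was on chromosome 21 from 38807526 to 38807715 (17.1-fold, 31 tags). It was followed by regions on chromosome 9 from 103174009 to 103174173 (16.4-fold, 32 tags), chromosome 2 from 88899705 to 88899879 (16.2-fold, 35 tags) and chromosome 2 from 92290496 to 92290603 (15.8-fold, 25 tags). The other 6 lay on chromosome 8 from 46852424, chromosome 4 from 9693355, chromosome 15 from 86338133, chromosome 16 from 46865399, chromosome 7 from 26240425 and chromosome 7 from 83314359, at 14.3-fold to 15.4-fold. Of the 10, 9 were also called after dexamethasone, and 3 were called in the combination library. The exception, on chromosome 8 from 46852424 to 46852515 (15.4-fold, 24 tags), was absent from the dexamethasone list and present in the combination list. The highest vehicle region not called after estradiol was on the X chromosome from 134232855 to 134232982 (13.5-fold, 18 tags), followed by regions on chromosome 17 from 22261521 to 22261624 (12.5-fold), chromosome 1 from 169863394 to 169863510 (12.1-fold), chromosome 1 from 29529428 to 29529585 (11.9-fold) and chromosome 12 from 50419233 to 50419350 (11.9-fold).

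**Figure D2:**
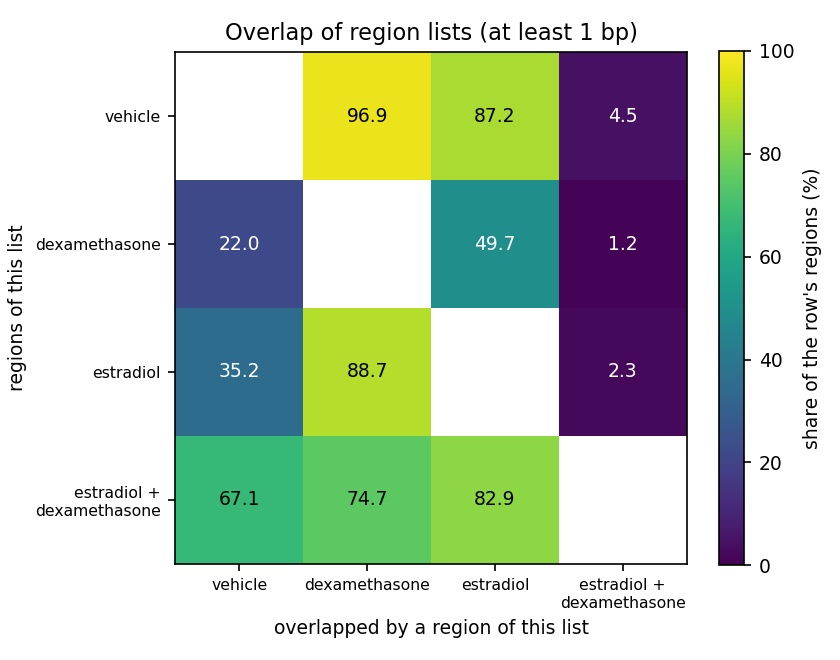
Share of each library's regions (rows, %) that overlap a region of each other library (columns) by at least 1 bp. Vehicle regions were mostly contained in the dexamethasone (96.9%) and estradiol (87.2%) lists, while the combination list overlapped 4.5% of them.

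The 2 hormones were then set side by side. Most regions called after estradiol were also called after dexamethasone, and about as many dexamethasone regions were shared with estradiol as were not. Of the 4772 estradiol regions, 4235 overlapped a dexamethasone region (88.7%, 87.8 to 89.6), and of the 8428 dexamethasone regions 4189 overlapped an estradiol region (49.7%, 48.6 to 50.8). Random placement gave 0.142% and 0.0792%. Of the strongest 10% of nuclear dexamethasone regions, 96.4% were called after estradiol (95.0 to 97.6), and of the weakest 10% 18.8% (16.2 to 21.6). At equal length, 69.1% of the estradiol regions overlapped one of the strongest 4772 dexamethasone regions. After merging the vehicle, dexamethasone and estradiol lists, 1648 of 8987 regions were in all 3 lists, 2527 in both hormone lists without vehicle, 4038 in dexamethasone alone, 516 in estradiol alone and 38 in vehicle alone.

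The gains of the 2 hormones share the same vehicle library, so part of the overlap between them comes from that library. Over the 8979 merged nuclear regions, 6565 were gained with dexamethasone, 3043 with estradiol and 2527 with both. Independent draws of these sizes from all 8979 regions would share 2225. The 8979 include regions called in vehicle, which cannot be gained, so 2225 is too low a value for independence. In 200 simulations in which a region kept 1 density in all 3 libraries, a mean of 1552 regions (1431 to 1645) was called with both hormones and not with vehicle. That density was taken only from the libraries that called the region, where heights are selected to be high. Libraries without a call did not lower it, so the simulations do not give the count for unchanged regions. The independent value also counts only regions called in at least 1 list, and the vehicle library could not be split. Neither value is therefore a baseline from which a shared effect could be measured.

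**Figure D3:**
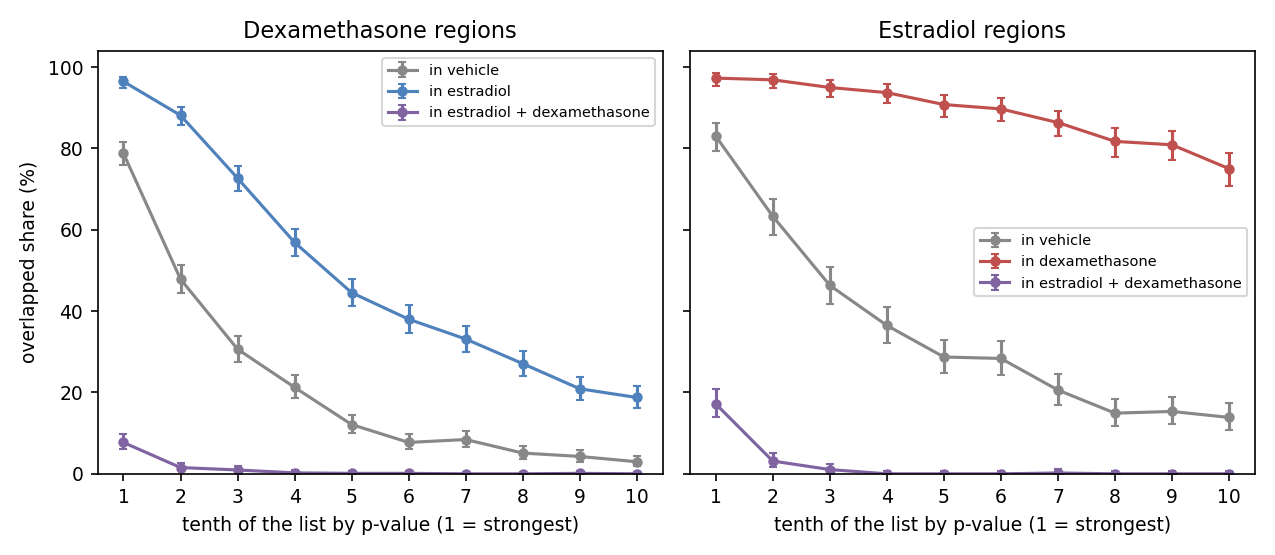
Share of the nuclear dexamethasone regions (left) and estradiol regions (right) that overlap a region of each other library (%, vertical axis), by steps of 10% of the list ranked by p-value (horizontal axis, 1 is the strongest), with 95% Clopper-Pearson intervals. For dexamethasone regions the share called in vehicle went from 78.8% in the strongest 10% to 2.97% in the weakest.

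The combination of estradiol and dexamethasone was compared with vehicle and with each hormone alone. Very few regions were called, and most of those were regions that other libraries also held. Of the 146 regions, 98 overlapped a vehicle region (67.1%, 58.9 to 74.7), 109 a dexamethasone region (74.7%, 66.8 to 81.5) and 121 an estradiol region (82.9%, 75.8 to 88.6). In random placements these shares had means of 2.07%, 1.92% and 1.88%. Conversely, 1836 of the 1923 vehicle regions, 8330 of the 8428 dexamethasone regions and 4662 of the 4772 estradiol regions had no counterpart, and the regions gained against these lists numbered 48, 37 and 25. At equal list length, 94, 116 and 87 regions were lost and 86, 112 and 79 gained, and without regions that had a neighbour within 10 kb, a filter chosen after seeing the data, 29, 23 and 16 were gained. The regions that remained were among the strong ones: of the strongest 10% of nuclear vehicle regions, 29.2% were called in the combination library (22.8 to 36.1), against 4.17% of the next 10% (1.82 to 8.04). This library had 8240912 tags and a modelled fragment length of 51 bp, close to the 50 bp tag. Of its 146 regions, 11 were mitochondrial, where vehicle had 8, dexamethasone 7 and estradiol 7. On the Y chromosome the combination library had 5 regions, where vehicle had 1, dexamethasone 2 and estradiol 4. Of its regions, 41.1% had another region of the same list within 10 kb (33.0 to 49.5), against 6.45% with vehicle (5.39 to 7.64), 16.6% with dexamethasone (15.8 to 17.4) and 12.0% with estradiol (11.1 to 13.0). Random placement gave means of 7.65%, 1.88%, 5.97% and 3.63% in the same order. Placement kept each region on its own chromosome. The 11 mitochondrial combination regions (7.53% of the list) were thus re-placed within 0.0165 Mb, where neighbours are nearly certain. They entered the observed 41.1% and the random overlap shares of this list too, so these random values do not describe nuclear regions alone.

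Merging all 4 lists gave 83 regions present in every library. Neither these regions nor those named below were checked for mapping artefacts. Ranked by fold enrichment in vehicle, the highest lay on chromosome 11 from 85195010 to 85195199 (25.4-fold, 55 tags), chromosome 1 from 569839 to 570015 (22.04-fold, 74 tags), chromosome 7 from 61969261 to 61969448 (21.8-fold, 55 tags), chromosome 1 from 91852785 to 91853148 (21.1-fold, 57 tags) and chromosome 17 from 33478114 to 33478324 (20.2-fold, 41 tags). The 10 highest combination regions without a vehicle counterpart were on chromosome 8 from 46852451 and 43092883, chromosome 2 from 92275922, 92290518, 89853206 and 133012827, chromosome 3 from 178941888, chromosome 10 from 98561350, chromosome 9 from 66833155 and chromosome 21 from 9696123, with fold enrichments from 13.8 to 17.3. Of these, 4 were called after dexamethasone and 6 after estradiol. The highest vehicle regions absent from the combination list were on chromosome 5 from 145582923 to 145583193 (17.6-fold, 37 tags), chromosome 7 from 30544436 to 30544688 (15.5-fold, 31 tags), chromosome 10 from 85899100 to 85899316 (15.1-fold, 34 tags), chromosome 8 from 9413198 to 9413407 (14.99-fold, 33 tags) and chromosome 8 from 580970 to 581180 (14.9-fold, 35 tags). All 5 were called after dexamethasone and after estradiol.

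The design also sets dexamethasone without estradiol beside dexamethasone with estradiol. Without estradiol, the dexamethasone library had 4.38 times as many regions as vehicle, with 1.40 times as many tags. With estradiol, the library that also received dexamethasone had 0.0306 times as many regions as estradiol alone, with 0.408 times as many tags. The 2 ratios lay on opposite sides of 1. With 1 library in each arm their difference could not be tested, and the second ratio rests on the combination library, which had the fewest tags and the shortest fragment length.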

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

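All tests of depth by call probability were chosen or given their final rule after related totals had been seen. That rule first asked only for 90%, which 5 of 5 estradiol regions met in the combination library. The interval condition was added later, and a looser bar that the 88.0% below would have passed was tried and withdrawn. The comparison of regions with and without neighbours was also chosen after, in place of a criterion written when the share of combination regions with a neighbour (41.1%) was known. The test of a library-wide factor was set before its value was seen. Ratios of region counts lay on opposite sides of 1 with and without the other hormone. The dexamethasone library had 4.38 times as many regions as vehicle, and the combination library 0.0306 times as many as estradiol. The estradiol library had 2.48 times as many regions as vehicle, and the combination library 0.0173 times as many as dexamethasone. The differences were not tested, since each arm had 1 library, and both ratios below 1 involve the same combination library, so they do not establish the direction of a hormone effect.

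The first pattern is the list of 146 combination regions. Fewer tags and a shorter fragment length stay open: 100% of the regions with a call probability above 0.95 were called, but these were 5 estradiol regions (interval 47.8 to 100) and 9 dexamethasone regions (66.4 to 100). From the heights as deposited, tags alone predicted 1332 estradiol, 1362 vehicle and 4589 dexamethasone regions, and tags with fragment length 402, 412 and 1703, the latter falling to 148, 161 and 757 with heights lowered by 1 counting SD, and 80.6, 86.5 and 450 with 1.5 SDs, where 103, 80 and 91 were called; the reductions are assumed and were chosen after related totals were seen. Signal kept at clustered hotspots stays open: 6.89% of estradiol regions with a neighbour within 10 kb were called (4.95 to 9.30), against 1.52% of those without (1.18 to 1.94), but the test is void, since the clustering of the combination list and its overlap with estradiol nearly fixed this order. The combined treatment cannot be told apart from a weak library, with 1 library.

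The second pattern is the excess of dexamethasone over vehicle regions. Depth alone is argued against: of the 2430 dexamethasone regions with a call probability above 0.95 at the vehicle library's tags and fragment length, 54.0% were called in vehicle (52.0 to 56.0), and the deeper estradiol library also had fewer regions than dexamethasone. In all 1846 were called, where tags alone predicted 6143 and tags with fragment length 6930 from the heights as deposited, and 4814 or 3502 for the latter with heights lowered by 1 or 1.5 SDs. The shortfall was not particular to vehicle. In the deeper estradiol library, 58.3% of 6516 such dexamethasone regions were called (57.1 to 59.5). In all 4182 were called there, where tags with fragment length predicted 8165 from the heights as deposited. A library-wide difference in signal over background, fitted as a factor of 0.549, stays open: 0 of the 18 regions that it gives a call probability above 0.95 were missing. The 200 simulations made for this test gave a median of 6 missing regions (1 to 13). They selected other and larger sets of regions, so this is not a range for the observed count and the test is void. Dexamethasone itself also stays open, untested, with 1 library for each treatment.

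The third pattern is the excess of estradiol over vehicle regions. The 1.89 times larger number of tags stays open: of the 292 estradiol regions with a call probability above 0.95 at the vehicle library's tags and fragment length, 88.0% were called there (83.7 to 91.5), between the 75% and 90% bounds. In all 1673 were called, where tags alone predicted 2152 and tags with fragment length 2933 from the heights as deposited, and 1620 or 1022 for the latter with heights lowered by 1 or 1.5 SDs. In the reverse direction, 88.1% of the 1777 vehicle regions with such a probability were found with estradiol (86.5 to 89.5), so 212 were missing although the estradiol library was deeper. Estradiol treatment itself stays open, untested, with 1 library for each treatment.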

How the results depend on the processing

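No paired analysis was possible because each treatment had 1 library, and for the same reason no library could be left out within a treatment. Of 161 recomputed values, 122 stayed within 1.5 times (counts, ratios) or within the interval of the main value (shares), and neither ratio of region counts turned its direction. Keeping fold enrichments of at least 5, or chromosomes 1 to 22 and X, moved none of 28 values each. These filters kept nearly whole lists: 1913 and 1914 of 1923 vehicle regions, 8420 and 8419 of 8428 dexamethasone regions, 4764 and 4761 of 4772 estradiol regions, and 135 and 130 of 146 combination regions. They are thus a weak check, and the ratios of region counts were not recomputed at matched depth. With a −log10 q of at least 10, the share of vehicle regions found with estradiol was 85.2%, that of dexamethasone regions found in vehicle 19.9%, with estradiol 47.0% and with the combination 0.854%, and that of estradiol regions found in vehicle 33.1% and with the combination 1.88%. When at least 50% of the shorter region had to overlap, 95.8% of vehicle regions were found with dexamethasone and 84.5% with estradiol, and 87.5% of estradiol regions with dexamethasone. With regions extended by 500 bp, 23.5% of dexamethasone regions were found in vehicle and 52.3% with estradiol, and 37.1% and 89.8% of estradiol regions in vehicle and with dexamethasone. Equal list lengths moved all 22 values, since by construction they shorten the longer list: vehicle regions were found at 60.6% (dexamethasone), 57.5% (estradiol) and 35.6% (combination), dexamethasone regions at 60.0% (vehicle), 68.1% (estradiol) and 20.5% (combination), estradiol regions at 57.2% (vehicle), 69.1% (dexamethasone) and 40.4% (combination), and combination regions at 41.1% (vehicle), 23.3% (dexamethasone) and 45.9% (estradiol). Gained and lost regions then numbered 770 and 757 for dexamethasone, 824 and 818 for estradiol, and for the combination 86 and 94 against vehicle, 112 and 116 against dexamethasone, and 79 and 87 against estradiol. Chosen after seeing the data, and after a first form that also filtered the comparison list was dropped because it counted regions with a removed partner as lost, leaving out counted regions with a neighbour within 10 kb left 29, 23 and 16 combination regions gained against vehicle, dexamethasone and estradiol, and leaving out the combination library raised the regions in every list from 83 to 1648. The alternatives set out for motifs, gene lists and genomic location were not run, because an hg19 genome and annotation were not used here. Depth limits the absence of a region from a list: it means below the threshold of that library and not closed chromatin.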

Other observations

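All windows and regions of this part, and its tests against random placement, were chosen after the values were seen. The 1 Mb window of chromosome 12 from 6 Mb held 24 dexamethasone, 19 estradiol and 10 vehicle regions, and the window from 56 Mb held 23, 15 and 12. In 1000 random placements on the same chromosomes, the highest window anywhere held at most 18 dexamethasone, 15 estradiol and 10 vehicle regions. The dexamethasone counts of both windows, the estradiol count of the first and the vehicle count of the second lay above these values, and the other 2 counts equalled them. Placement was uniform along each chromosome and did not follow gene density or mappability. An excess over it therefore does not show that these windows are unusual for open chromatin. The windows of chromosome 10 from 99 Mb, with 16 dexamethasone, 13 estradiol and 10 vehicle regions, and of chromosome 13 from 111 Mb, with 16, 10 and 5, did not exceed them. Chromosome 12 held 8.79% of the vehicle regions (7.56 to 10.1), 6.60% of the dexamethasone regions (6.08 to 7.15) and 6.94% of the estradiol regions (6.23 to 7.69). Apart from the mitochondrial genome, chromosome 19 had the highest density of dexamethasone regions, with 5.81 per Mb of the span covered by calls.

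The window of chromosome 10 from 42 Mb held 10 regions of the combination library, against 9 with estradiol, 3 with dexamethasone and 1 with vehicle. The windows of chromosome 6 from 58 Mb and chromosome 21 from 9 Mb held 7 combination regions each. The first also held 6 estradiol, 6 dexamethasone and 4 vehicle regions, and the second 4 of each. The windows of chromosome 12 from 6 Mb and from 56 Mb held 0 and 1 combination regions, and that of chromosome 10 from 99 Mb held 0. Of the merged regions, 20 were called in the combination library alone, 5 of them on chromosome 10 and 3 on chromosome 18. A pair of them lay on chromosome 3, from 178928018 to 178928068 (9.13-fold, 12 tags) and from 178941888 to 178941956 (16.1-fold, 22 tags).

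Among regions in dexamethasone and in neither vehicle nor estradiol, the highest after those on chromosomes 12 and 7 lay on chromosome 2 from 152708413 to 152708552 (16.4-fold, 28 tags), chromosome 2 from 109335758 to 109335993 (15.8-fold, 23 tags) and chromosome 4 from 89658875 to 89659026 (15.4-fold, 29 tags).

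The highest mitochondrial region of each library lay at or within 1 tag of the ceiling of the method. With 1 tag kept per position and strand, a base can be covered by at most 2 tags for each base of the fragment length. The highest mitochondrial pileup was 207 with vehicle, 178 with dexamethasone, 168 with estradiol and 101 with the combination, where that ceiling was 208, 178, 168 and 102. Other mitochondrial regions lay lower, such as those called in the combination library alone, with 94 and 96 tags.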
